A study of Homo sapiens with 4 samples.

How the data were processed

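Gene expression was measured by bulk RNA sequencing in 4 libraries of human CD34-positive cells grown as erythroid progenitors, 2 with vehicle and 2 with TGF-β1, on day 6 of culture and 12 h after treatment. Titles, sample characteristics and the design text name TGF-β1, and a second line of the treatment protocol names TGF-β2, which no sample title carries. Per the labels' protocols, RNA was extracted with a column kit, checked for integrity, made into stranded libraries and sequenced in paired ends on an Illumina NextSeq 500. The submitters' processing notes name TopHat2 and the genome build GRCh38 (hg38); the counting program, its strand setting and the gene annotation are not given in the sources used here. The deposited files hold raw counts of reads or fragments per gene, whole numbers with no normalization, 1 file per library.

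The files list 60725 gene identifiers, of which 57055 were matched without the version number to GENCODE release 29 on GRCh38, which gave the symbols, coordinates and gene lengths. The annotation the authors used may be another, so 3670 identifiers have no name here. Also present were 97 spike-in rows, all at 0, and 649 rows with a numeric identifier that nothing in the files explains, holding between 262 and 369 counts per library. A further 5 rows are totals of reads not assigned to a gene. All these rows were left out of library sizes and tests. Reads outside annotated genes were 22.0%, 22.7%, 23.5% and 25.0% of the assigned, ambiguous and unassigned counts in vehicle 1, TGF-β1 1, vehicle 2 and TGF-β1 2, and ambiguous reads were 6.15%, 6.50%, 6.25% and 6.24%. Genes of the Y chromosome, XIST and TSIX were also left out of every fit and table.

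Gene counts summed to 43309173, 37455074, 29221868 and 36989023 in the same order. A floor of 3 counts corresponded to 0.0693, 0.0801, 0.103 and 0.0811 CPM. Floors and counting intervals cover counting error only, since reads carry no molecular identifiers here. The 10 most abundant genes took 5.74% to 7.70% of the counts. Replicates of a group differed by far more than counting noise, with a chi-square per degree of freedom of 60.2 between the vehicle and 73.9 between the TGF-β1 libraries, so none was counted as a repeat of another.

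The main test was edgeR 4.0.16 (quasi-likelihood, robust, TMM factors, filterByExpr) on 21187 genes with treatment as the only term, two-sided, with Benjamini-Hochberg adjustment at 0.05. A permutation test of a single gene in 2 against 2 libraries cannot go below p = 0.333. The labels call the replicates independent biological replicates, and the design text states no pairing. The library names carry one prefix in both libraries of replicate 1 and another in both libraries of replicate 2, which was taken as a batch mark, although its meaning is not stated. The difference of replicate 2 from replicate 1 correlated between the vehicle and the TGF-β1 libraries across genes (Pearson r = 0.811). The first principal component of log2 CPM, with 70.7% of the variance, separated the replicate numbers, and the second, with 21.9%, the treatments. Within-replicate folds and the fit with the replicate number as a block are therefore printed beside the main result. The decision to lead with the blocked calls came after the counts of both fits were known.

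Alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1), other library scalings, other filters on low counts, robust=FALSE, glmTreat at a fold of 1.2, removal of globin and mitochondrially encoded genes, and each library left out in turn, all in R 4.3.3. Combinations of the block with other choices were added after the data were seen. Levels are TMM-scaled CPM, given as mean ± SD over 2 libraries, and folds within a replicate are ratios of CPM with a prior count of 2. Log2 changes with their SE come from edgeR with the block unless stated otherwise. The SE was derived from the log2 change and the F statistic of the test. With a median of 247 prior degrees of freedom it rests mostly on the spread shared across genes. It does not measure how far the changes of the 2 replicates lie apart, which the folds within replicates show.

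In total 34 gene lists, fixed before the data were examined, were tested with limma's camera at a preset correlation of 0.01 between genes, with adjustment over the lists, and again with an estimated correlation and with fry. Camera without the block called 8 lists higher and 5 lower, and with the block 9 and 5. With an estimated correlation 0 lists passed in either fit. Where genes were adjusted over a list alone, the other lists were not counted. The genes named are a fixed set of erythroid and TGF-β genes, up to 4 members of each list described, chosen by smallest p, and the 12 largest rises and 12 largest falls among called genes of mean CPM of at least 5 whose 4 libraries separate by treatment. The last part named none in the main fit, so it was applied to the blocked fit after the values were seen. Single further members named beside list counts were also chosen after their values were seen. In the end 3 of these genes are not reported here, and the list counts and tests include them.

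The fits were tested on simulated counts with 200 genes changed, of about 20770 tested in edgeR and limma-voom and 21190 in DESeq2. Means and library sizes came from these libraries. Both treatments were given the same offset between replicate numbers, each gene the same fold in both replicates, and the spread came from the blocked fit. That setup favours the block by design. It cannot show that a block suits these data, and it does not cover folds that differ between replicates. With the block, edgeR called 17.9% of genes changed 1.5-fold, 91.0% of those changed 2-fold and 100% of those changed 4-fold, and 10.3% of its calls were false; robust=FALSE gave 94.0% at 2-fold and 10.2% false. Without the block edgeR called 0 of them at any of these folds, while DESeq2 without it called 1.49%, 49.3% and 97.0%, with 2% of its 100 calls false. DESeq2 with the block called 38.8%, 98.5% and 100%, with 17.3% of calls false. With no gene changed the blocked edgeR fit made 0 calls. Camera with the estimated correlation missed a simulated list of 40 raised genes (adjusted p = 0.0606 without and 0.977 with the block), so a list that fails it here is not shown to be unchanged. Camera with the preset correlation found it and called 0 of 30 random lists. The simulated genes were drawn independently, so this cannot show how often lists of genes that vary together are called falsely. In the data the correlation estimated without the block was 0.832 for the globin and 0.643 for the heme list. It was 0.0188 for the TGF-β/SMAD response and -0.00158 for the MYC target list. Without the block the offset between replicate numbers enters these estimates. The adjusted p-values with an estimated correlation printed for single lists of the data also come from the fit without the block.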

Results

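The data are gene counts from bulk RNA sequencing of human erythroid progenitors. CD34-positive cells, which are blood stem and progenitor cells, were cultured toward the red cell lineage and used on day 6 of culture. The cultures received vehicle or the cytokine TGF-β1, and RNA was collected 12 h later. Each treatment had 2 libraries, described by the submitters as independent biological replicates. Counts assigned to genes came to 43309173 in vehicle replicate 1, 37455074 in TGF-β1 replicate 1, 29221868 in vehicle replicate 2 and 36989023 in TGF-β1 replicate 2. Between 30985 and 32367 genes had at least 1 count in a library. Globin genes took 0.711% and 0.997% of the counts in vehicle and TGF-β1 replicate 1, and 1.54% and 1.91% in replicate 2.

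The comparison asks which genes of day 6 erythroid progenitors are higher or lower 12 h after TGF-β1, with the β-globin genes and MYC named in the title of the series. The inhibitor of TGF-β signalling SMAD7 was 8.29-fold and 4.01-fold higher with TGF-β1 in replicates 1 and 2, and ID2, an inhibitor of basic helix-loop-helix factors, 2.96-fold and 3.51-fold. MYC fell to 0.704 and 0.752 of its vehicle level, and 46 of 58 MYC target genes fell with it, or 29 in blocked DESeq2. The globin HBD, the heme enzyme ALAS2 and the anion exchanger SLC4A1 rose, as did HBB by a smaller amount. HBB did not pass in blocked DESeq2 (adjusted p = 0.0623), and the libraries of HBB, ALAS2 and SLC4A1 do not separate by treatment. All these calls come from a fit with the replicate number as a block, put first after the counts were seen. The main edgeR fit without the block called 0 genes. KIT and MYB fell, though the progenitor-stage list moved both ways, with 5 of 16 up and 6 down. Of 21 glycolytic genes 14 fell, while 9 of 22 interferon response genes rose and 0 fell. No list passed with an estimated correlation between genes.

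In the text on genes, rose and fell are used where edgeR's quasi-likelihood test passed an adjusted p of 0.05 with the replicate number as a block. The library names in the labels carry a common prefix within each replicate number, and the labels do not say what it marks. That blocked fit, planned as an alternative before the data were examined, called 1740 genes higher and 1617 lower of 21187 tested, and DESeq2 with the block called 659 and 607. Of these, 1252 genes were called by edgeR, DESeq2 and limma-voom alike. Without the block, as the main design has it, edgeR called 0 genes, limma-voom called 0 and DESeq2 called 89 higher and 12 lower. In that edgeR fit 822 genes had an unadjusted p under 0.05, less than the share of 0.05 that no change would give. The blocked calls rest on 1 residual degree of freedom per gene and on the spread shared across genes. They were set beside the unblocked counts after both had been seen. Without the block, 14 of the 106 named genes turned sign when 1 library was left out, among them KIT, SLC4A1, HBA1 and HBA2. Of the 106 named genes, HBB, HBG1, HBA1, TAL1, UHRF1, MCM4, CDT1, GADD45B, SESN2 and PFKP, called by blocked edgeR, did not pass in blocked DESeq2. Genes named later, after their values were seen, are not among the 106.

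Within the replicate numbers, the log2 changes of the 21187 genes correlated across genes at a Pearson r of 0.497, with a Spearman rho of 0.419. Genes are not independent replicates, so no p-value is given. Among 11711 genes with a mean CPM (counts scaled to library size) of at least 5, 93 were at least 2-fold apart in both replicates. Of these, 76 were higher in both, 17 were lower in both and 0 went in opposite directions. The blocked edgeR fit called 84 of the 93, and it called 93 with edgeR's robust=FALSE, as did blocked DESeq2.

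**Figure D1:**
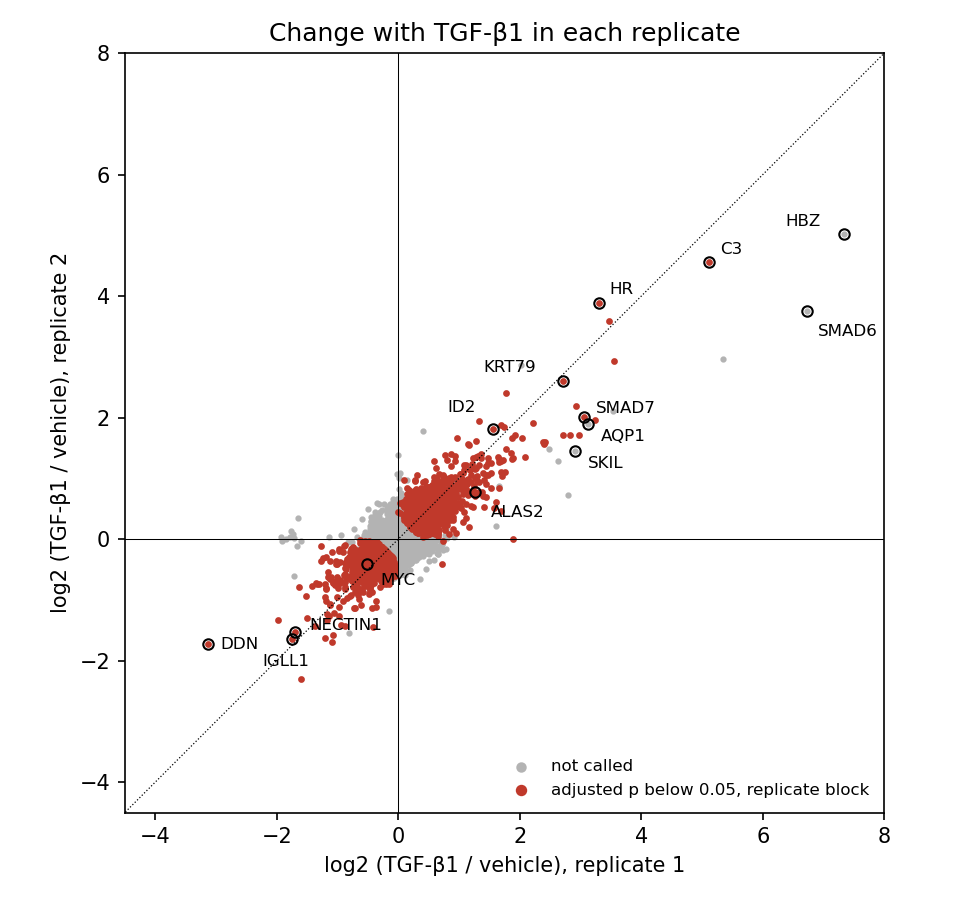
Each point is 1 of the 11711 genes with a mean CPM of at least 5, with the log2 change from vehicle to TGF-β1 in replicate 1 on the horizontal axis and in replicate 2 on the vertical axis. Red points passed an adjusted p of 0.05 in edgeR with the replicate block; SMAD6, HBZ, SKIL and AQP1 lie far out in both replicates with folds of unequal size and are grey, having adjusted p from 0.227 to 0.391, though they passed with robust=FALSE.

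Of 32 tested members of the list of TGF-β/SMAD response genes, 15 rose, 3 fell and 14 did not pass, and the counts were 15 and 3 when adjusted over the list alone. Blocked DESeq2 had 13 up and 0 down. SMAD7 (ENSG00000101665.8, protein coding, chromosome 18, 48919853 to 48952052, minus strand, GRCh38) went from 2.14 ± 0.0989 CPM with vehicle to 13.3 ± 6.03 with TGF-β1 (SD, n = 2), a log2 change of 2.63 ± 0.17 (SE; adjusted p = 2.94e-20, edgeR with the block). The AP-1 subunit JUNB rose 3.15-fold and 2.51-fold in the 2 replicates, and TGFB1 itself 1.25-fold and 1.21-fold. Exons of JUNB and TGFB1 overlap other genes on the opposite strand, and the strand setting of the counting is not given in the sources used here.

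SKIL, a repressor of SMAD activity, went from 34.1 to 256 CPM in replicate 1 and from 65.1 to 178 in replicate 2. SMAD6 went from 1.47 to 162 and from 31.1 to 420 CPM. Both were higher in both replicates by unequal folds, 7.51 and 2.73 for SKIL and 106 and 13.5 for SMAD6. The blocked edgeR fit gave them adjusted p = 0.391 and 0.341, blocked DESeq2 gave 0.0218 and 0.000615, and blocked edgeR with robust=FALSE gave 1.59e-58 and 1.10e-97. The list as a whole passed the camera test in limma (adjusted p = 0.000137; 0.000406 with the block), and had adjusted p = 0.654 with an estimated correlation. Without the block and adjusted over the list alone, 6 of its members passed in edgeR, all higher: SMAD7, PMEPA1, SKIL, LTBP3, LDLRAD4 and JUNB. PMEPA1 and LTBP3 were named after their values were seen.

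All 3 tested ID genes, targets of BMP and TGF-β signalling, rose with the block in edgeR and in DESeq2, and all 3 passed without it when adjusted over the list alone (adjusted p = 0.0248 in edgeR). ID2 (ENSG00000115738.9, protein coding, chromosome 2, 8678845 to 8684453, plus strand, GRCh38) went from 58.6 ± 31.1 to 184 ± 78.1 CPM (SD, n = 2), a log2 change of 1.68 ± 0.08 (SE; adjusted p = 1.25e-52, edgeR with the block). ID1 rose 3.05-fold and 1.53-fold. ID3 had 34 and 385 counts in vehicle and TGF-β1 replicate 1, and 2 and 109 counts in replicate 2. The replicate 2 ratio of scaled ID3 counts was 43.0, with an exact 95% counting interval from 11.6 to 360. The list passed camera (adjusted p = 0.000801; 0.00157 with the block; adjusted p = 0.778 with an estimated correlation). Exons of ID2 overlap its antisense gene.

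Among 20 TGF-β receptors, ligands and SMADs, 4 rose and 5 fell, or 5 and 6 when adjusted over the list alone and 3 and 2 in blocked DESeq2. The risers were SMAD7, TGFB1 and the type I receptors BMPR1A and ACVR1. Those that fell were the receptor TGFBR2, the activin receptor ACVR2B, the co-receptor ENG and the signal transducers SMAD1 and SMAD3. Their values lay between a log2 change of -0.48 for SMAD3 and 2.63 for SMAD7. In blocked DESeq2 the 3 risers were SMAD6, SMAD7 and TGFB1. BMPR1A and ACVR1 therefore did not pass there, and SMAD3 did not either. The 2 genes down there included ENG (adjusted p = 0.000782), so most of TGFBR2, ACVR2B and SMAD1 did not pass. The list did not pass camera (adjusted p = 0.676), with a median log2 change of -0.03 and a mean of 0.35, and its direction turned without vehicle replicate 1 (adjusted p = 0.514) and without TGF-β1 replicate 2 (adjusted p = 0.451). BMPR1A, ACVR1, ACVR2B, TGFBR2, SMAD1 and SMAD3 were named after their values were seen.

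MYC (ENSG00000136997.15, protein coding, chromosome 8, 127735434 to 127741434, plus strand, GRCh38) fell from 443 ± 16.4 to 322 ± 3.13 CPM (SD, n = 2). Its log2 change was -0.46 ± 0.07 (SE; adjusted p = 4e-08 in edgeR with the block and 6.52e-06 in DESeq2 with the block; unadjusted p = 0.00774 in edgeR without it). Of 58 tested MYC targets, mostly genes of ribosome assembly and nucleotide supply, 46 fell, 0 rose and 12 did not pass, and 48 fell when adjusted over the list alone. Blocked DESeq2 had 29 down and 0 up. In both replicates 53 of the 58 were lower. The nucleolar factors TCOF1, MYBBP1A, NOP16 and RRP12 fell to 0.722, 0.658, 0.718 and 0.689 of vehicle in replicate 1, and to 0.725, 0.732, 0.690 and 0.702 in replicate 2. The list median log2 change was -0.31 in replicate 1 and -0.35 in replicate 2.

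The MYC target list had the smallest camera p of the 34 lists (adjusted p = 1.07e-18; 7.34e-15 with the block), and adjusted p = 0.252 with an estimated correlation. Exons of MYBBP1A, NOP16 and RRP12 overlap genes on the opposite strand. Of 74 cytosolic ribosomal protein genes, 1 rose, 0 fell and 73 did not pass, and 0 passed when adjusted over the list alone or in blocked DESeq2 (camera adjusted p = 0.608). Among 11 members and partners of the MYC family, 2 rose and 1 fell, with the same counts adjusted over the list alone and 0 and 1 in blocked DESeq2 (camera adjusted p = 0.816).

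**Figure D2:**
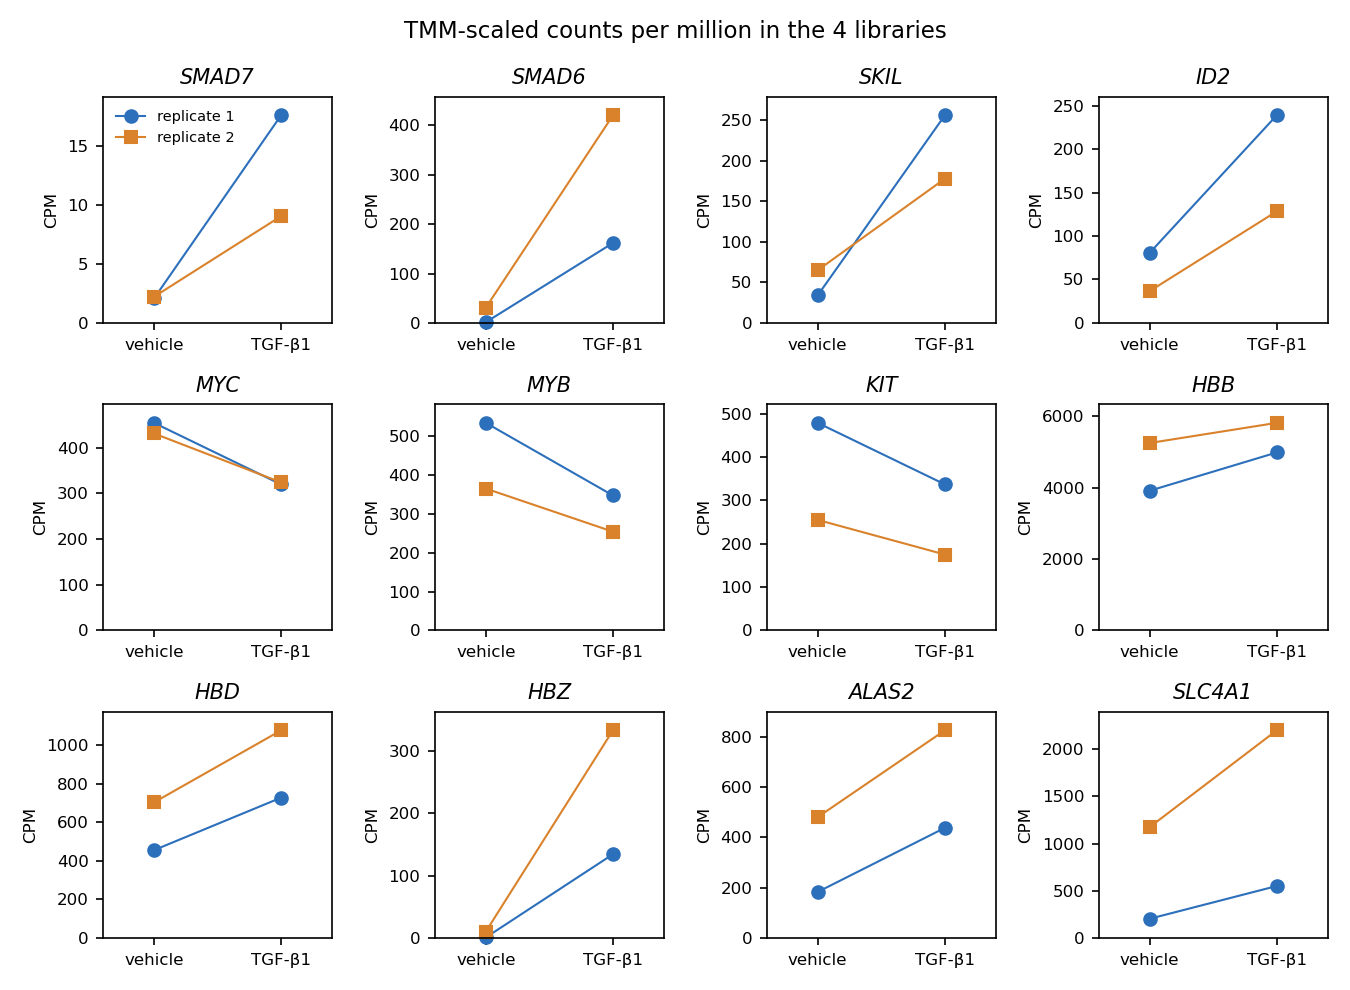
TMM-scaled CPM of 12 genes in the 4 libraries, each axis starting at 0; blue circles are replicate 1 and orange squares replicate 2, with a line joining the vehicle and TGF-β1 library of the same replicate number. MYC, MYB and KIT are lower and the other genes higher with TGF-β1 in both replicates. SLC4A1, HBB, ALAS2 and KIT differ more between the replicates than between the treatments.

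Of 10 globin genes, 6 rose and 0 fell, with the same counts adjusted over the list alone and 4 and 0 in blocked DESeq2. HBB (ENSG00000244734.3, protein coding, chromosome 11, 5225464 to 5229395, minus strand, GRCh38) went from 4585 ± 947 to 5404 ± 587 CPM (SD, n = 2), 1.27-fold and 1.11-fold within the replicates. Its log2 change was 0.25 ± 0.08 (SE; adjusted p = 0.0112 in edgeR with the block, 0.0623 in DESeq2 with the block; unadjusted p = 0.281 in edgeR without it). HBD, the minor adult β-like globin, rose 1.60-fold and 1.53-fold (adjusted p = 9.16e-15, edgeR with the block). Exons of HBD overlap HBBP1 on the same strand.

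The α-globin copies HBA1 and HBA2 were 1.61-fold and 1.59-fold higher in replicate 1, and each 1.30-fold higher in replicate 2. Blocked DESeq2 gave adjusted p = 0.272 for HBA1 and 2.56e-06 for HBA2. Between the vehicle libraries they differed more, from 1067 to 4217 CPM for HBA1. HBA1 and HBA2, and the fetal pair HBG1 and HBG2, are near-identical copies that share reads, so the single values are uncertain. HBG1 rose 1.60-fold and 1.18-fold. HBG2 did not pass, at 1.18-fold and 0.939-fold, nor did the embryonic HBE1, at 1.22-fold and 0.789-fold. The embryonic α-like gene HBZ went from 0.783 to 134 CPM and from 10.3 to 333 CPM, with adjusted p = 0.227 in blocked edgeR, 7.65e-120 there with robust=FALSE and 1.59e-07 in blocked DESeq2. Exons of HBZ overlap HBM on the same strand, and those of HBG2 and HBE1 overlap each other.

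The globin list passed camera with adjusted p = 0.0402, or 0.00157 with the block, and had adjusted p = 0.898 with an estimated correlation. Leaving out vehicle replicate 1 gave the globin list adjusted p = 0.919 in camera, and leaving out TGF-β1 replicate 2 gave 0.592. Those reduced sets, for this and every other list, compare libraries of unequal replicate numbers without the block. A loss, a pass or a turn of direction in them can come from the offset between replicate numbers. They therefore do not measure how firm the change with treatment is.

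Of 25 members of the list of heme synthesis and iron uptake genes, 11 rose, 0 fell and 14 did not pass, and 12 rose when adjusted over the list alone, or 8 in blocked DESeq2. ALAS2 (ENSG00000158578.18, protein coding, chromosome X, 55009055 to 55031064, minus strand, GRCh38), the erythroid enzyme that starts heme synthesis, went from 331 ± 210 to 631 ± 274 CPM (SD, n = 2). That was 2.39-fold and 1.72-fold within the replicates, a log2 change of 1.02 ± 0.08 (SE; adjusted p = 3.76e-14, edgeR with the block). The mitochondrial glycine carrier SLC25A38 rose 1.43-fold and 1.34-fold, ferrochelatase (FECH) 1.26-fold and 1.30-fold, and heme oxygenase HMOX1 2.52-fold and 3.86-fold. The transferrin receptor TFRC did not pass, at 1.05-fold and 0.975-fold. The list gave camera adjusted p = 0.0350, or 0.00116 with the block, and adjusted p = 0.898 with an estimated correlation. The camera p became 0.919 without vehicle replicate 1, and without TGF-β1 replicate 2 the direction turned, with adjusted p = 0.592. Exons of ALAS2 overlap APEX2 on the opposite strand.

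Of 29 red cell membrane and surface genes, 13 rose and 3 fell, or 13 and 4 when adjusted over the list alone and 12 and 1 in blocked DESeq2. SLC4A1, which encodes band 3, rose 2.71-fold and 1.87-fold, from 203 to 550 CPM in replicate 1 and from 1174 to 2199.9 CPM in replicate 2. The glucose transporter SLC2A1 rose 1.5-fold and 1.67-fold, and the blood group gene KEL 1.25-fold and 1.49-fold. RHCE, which shares reads with its copy RHD, rose 1.56-fold and 1.65-fold. The water channel AQP1 went from 7.53 to 66.0 and from 22.2 to 82.9 CPM, with adjusted p = 0.306 in blocked edgeR, 2.06e-58 there with robust=FALSE and 1.28e-26 in blocked DESeq2. The list passed camera with the block (adjusted p = 0.00626) and not without it (adjusted p = 0.127), and had adjusted p = 0.898 with an estimated correlation. Without the block, the direction turned when vehicle replicate 1 or TGF-β1 replicate 2 was left out. It stayed a rise when TGF-β1 replicate 1 or vehicle replicate 2 was left out. These runs set unequal replicate numbers against each other, so they cannot tell the treatment from the replicate offset.

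Of 17 genes of organelle clearance and autophagy in late erythroid cells, 7 rose and 1 fell, or 10 and 2 when adjusted over the list alone and 6 and 0 in blocked DESeq2. The autophagy genes GABARAPL1 and ULK1 rose 1.85-fold and 1.37-fold in replicate 1, and 1.57-fold and 1.49-fold in replicate 2. The ubiquitin ligase TRIM58 rose 1.65-fold and 1.47-fold, and the ubiquitin-conjugating enzyme UBE2H 1.41-fold and 1.42-fold. For the list, camera gave adjusted p = 0.00175, or 0.00239 with the block, and adjusted p = 0.778 with an estimated correlation. Without vehicle replicate 1 it gave adjusted p = 0.0616, and without TGF-β1 replicate 2 it gave 0.121.

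Among 19 erythroid transcription factors, 8 rose and 2 fell, with the same counts adjusted over the list alone and 5 and 2 in blocked DESeq2. GATA1 rose 1.24-fold and 1.26-fold, NFE2 1.39-fold and 1.42-fold, TAL1 1.10-fold and 1.23-fold, and FOXO3 1.85-fold and 1.73-fold. MYB fell to 0.650 and 0.696 of vehicle and LMO2 to 0.730 and 0.776. KLF1 and BCL11A did not pass, at 1.02-fold and 1.14-fold for KLF1 and 1.08-fold and 1.15-fold for BCL11A. The list did not pass camera (adjusted p = 0.251, or 0.0646 with the block). Its direction turned without vehicle replicate 1 and without TGF-β1 replicate 2, in runs that set unequal replicate numbers against each other.

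Genes marking earlier erythroid progenitors moved both ways. Of 16, 5 rose and 6 fell, or 5 and 7 when adjusted over the list alone and 4 and 5 in blocked DESeq2. The stem cell factor receptor KIT fell to 0.704 and 0.687 of vehicle (log2 change -0.52 ± 0.07, SE; adjusted p = 3.73e-10, edgeR with the block). The iron exporter SLC40A1 fell to 0.796 and 0.791 and ENG to 0.664 and 0.831, while APOE rose 1.82-fold and 1.63-fold and GATA2 1.30-fold and 1.2-fold. The erythropoietin receptor EPOR did not pass, at 1.00-fold and 1.15-fold. The list did not pass camera (adjusted p = 0.465). Its direction was a fall with every library in, and turned without vehicle replicate 1 and without TGF-β1 replicate 2. Those runs set unequal replicate numbers against each other.

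Markers of other lineages and of RNA quality were read beside these erythroid lists. Of 16 mast cell, basophil and eosinophil genes, 8 rose and 1 fell, or 10 and 1 when adjusted over the list alone and 7 and 0 in blocked DESeq2. The tryptase genes TPSB2 and TPSAB1, near-identical copies, rose 1.98-fold and 2.05-fold in replicate 1 and 1.87-fold and 1.82-fold in replicate 2, and TPSD1 rose 1.83-fold and 2.30-fold. TPSB2 also passed without the block when adjusted over the list alone (adjusted p = 0.0228 in edgeR), which takes no account of the other lists tested. ALOX5, the leukotriene-forming lipoxygenase, rose 2.29-fold and 1.69-fold. Camera gave the list adjusted p = 0.0398, or 0.00684 with the block, and adjusted p = 0.898 with an estimated correlation. Its direction turned without TGF-β1 replicate 1 (adjusted p = 0.862) and without vehicle replicate 2 (adjusted p = 0.956).

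The neutrophil and monocyte list had 6 of 22 genes up and 4 down (camera adjusted p = 0.926), and the megakaryocyte list 1 of 19 up and 2 down (adjusted p = 0.982, in the direction of a rise, with a median log2 change of -0.07). In the stem and early progenitor list, 2 of 19 rose and 4 fell (adjusted p = 0.552), or 3 and 6 when adjusted over the list alone. Of 8 lymphoid genes 1 rose and 2 fell (adjusted p = 0.405), and 1 and 3 when adjusted over the list alone. Of 6 stromal and endothelial genes 3 rose (adjusted p = 0.235). Adjusted over the list alone, the neutrophil, megakaryocyte and stromal counts were the same. Blocked DESeq2 had 1 up and 2 down in the neutrophil list, 0 and 2 in the megakaryocyte list, 0 and 2 in the stem list, and 0 and 0 in the lymphoid and stromal lists. Of 20 immediate early and heat shock genes, 6 rose and 3 fell, or 7 and 4 when adjusted over the list alone and 5 and 2 in blocked DESeq2 (camera adjusted p = 0.382). No replication-dependent histone gene passed of 13 tested (adjusted p = 0.902), with the same result adjusted over the list alone and in blocked DESeq2.

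Of 13 mitochondrially encoded genes, 11 rose and 0 fell, and 13 rose when adjusted over the list alone, or 8 in blocked DESeq2. MT-ND6 rose 1.18-fold and 1.39-fold and MT-CO3 1.21-fold and 1.19-fold, and together the mitochondrially encoded genes took 3.46% and 3.95% of the counts in replicate 1 and 3.84% and 4.79% in replicate 2. MT-ATP8 and MT-ND4L, which overlap their neighbours, rose 1.69-fold and 1.33-fold in replicate 1 and 1.27-fold and 1.16-fold in replicate 2. As a list they had camera adjusted p = 0.000801, or 0.000997 with the block, and adjusted p = 0.898 with an estimated correlation. Without vehicle replicate 1 its adjusted p was 0.220, and without TGF-β1 replicate 2 it was 0.341. Of 35 nuclear genes of oxidative phosphorylation, 0 rose and 1 fell (camera adjusted p = 0.251), and 0 passed when adjusted over the list alone or in blocked DESeq2.

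**Figure D3:**
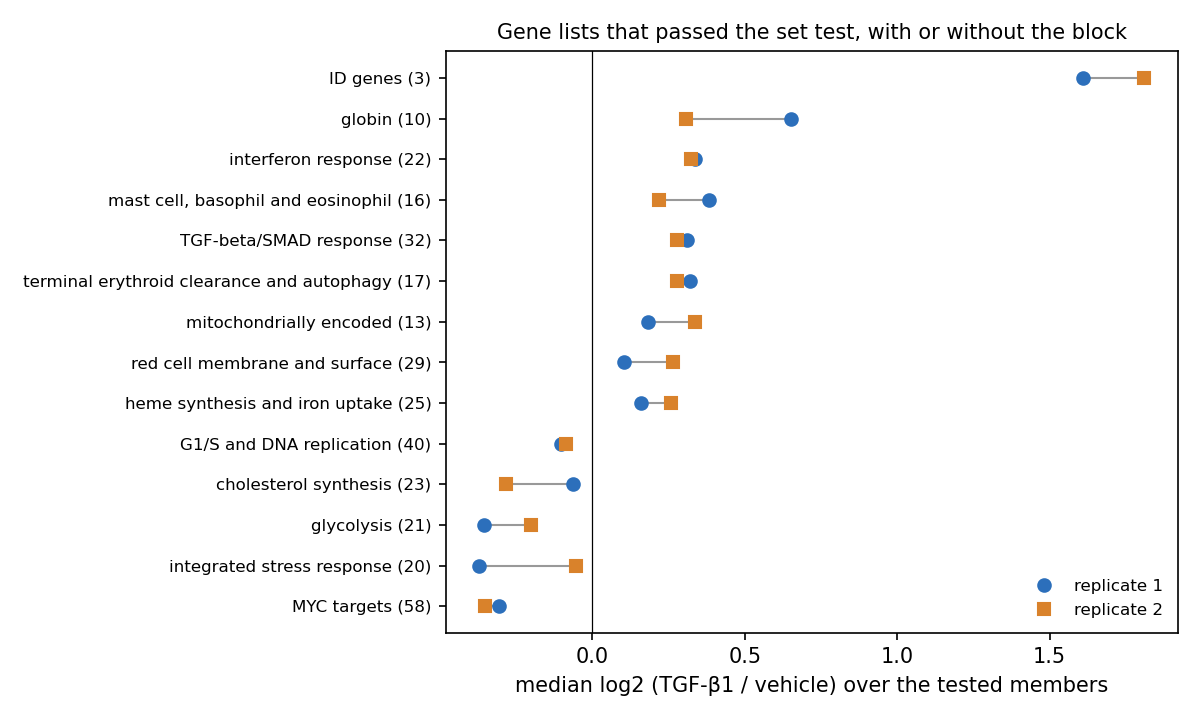
Median log2 change from vehicle to TGF-β1 over the tested members of each list (their number in brackets), for replicate 1 (blue circles) and replicate 2 (orange squares), for the 14 lists that passed camera at an adjusted p of 0.05 with or without the replicate block. All 14 medians have the same sign in both replicates, and the ID genes have the largest, 1.61 and 1.81; with an estimated correlation 0 lists passed.

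Of 22 interferon response genes, 9 rose and 0 fell, and 11 rose when adjusted over the list alone, or 6 in blocked DESeq2. IFI44L rose 3.17-fold and 2.62-fold from low vehicle levels of 1.47 and 1.97 CPM, IFI27 2.89-fold and 2.39-fold, IFI44 1.61-fold and 1.44-fold, and IFIT2 1.44-fold and 1.69-fold. The list gave camera adjusted p = 0.000103, or 0.000464 with the block, and adjusted p = 0.647 with an estimated correlation. Of 15 inflammatory cytokine and NF-κB genes, 2 rose and 7 fell, with the same counts adjusted over the list alone and 1 and 2 in blocked DESeq2 (camera adjusted p = 0.646; 0.108 with the block).

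Of 21 glycolytic genes, 14 fell and 2 rose, or 15 and 3 when adjusted over the list alone and 11 and 2 in blocked DESeq2. Phosphofructokinase PFKP fell to 0.841 and 0.873 of vehicle, hexokinase HK2 to 0.772 and 0.815, and triosephosphate isomerase TPI1 to 0.782 and 0.881. SLC2A1, a member of this list and of the membrane list, rose. Camera gave the glycolytic list adjusted p = 0.0308, or 0.00239 with the block, and adjusted p = 0.898 with an estimated correlation. Without vehicle replicate 1 it gave adjusted p = 0.907, and without TGF-β1 replicate 2 it gave 0.398.

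Of 23 genes of cholesterol synthesis, 6 fell, 1 rose and 16 did not pass, or 10 fell and 1 rose when adjusted over the list alone, and blocked DESeq2 had 3 down and 1 up. The sterol reductase DHCR7 fell to 0.792 of vehicle in replicate 1 and to 0.639 in replicate 2. Lanosterol synthase (LSS) fell to 0.640 and 0.770, while the sterol carrier STARD4 rose 1.74-fold and 1.37-fold. As a list the sterol genes had camera adjusted p = 0.00299, or 0.00591 with the block, and adjusted p = 0.823 with an estimated correlation. It gave adjusted p = 0.0616 without vehicle replicate 1 and 0.288 without TGF-β1 replicate 2.

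Of 20 genes of the integrated stress response, 9 fell and 2 rose, with the same counts adjusted over the list alone and 5 and 2 in blocked DESeq2. The serine pathway enzymes PSAT1 and SHMT2 fell to 0.686 and 0.767 of vehicle in replicate 1 and to 0.640 and 0.857 in replicate 2. MTHFD2, an enzyme of mitochondrial folate metabolism, fell to 0.780 and 0.805, and the stress sensor SESN2 to 0.597 and 0.814. The list gave camera adjusted p = 0.0122, or 0.00684 with the block, and adjusted p = 0.778 with an estimated correlation. Without vehicle replicate 1 its adjusted p was 0.118, and without TGF-β1 replicate 1 it was 0.0882.

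Of 40 genes of the G1/S transition and DNA replication, 8 fell and 1 rose, or 9 and 1 when adjusted over the list alone and 3 and 0 in blocked DESeq2. UNG fell to 0.783 and 0.712 of vehicle, CDT1 to 0.779 and 0.922, MCM4 to 0.840 and 0.883 and UHRF1 to 0.811 and 0.895. The median log2 change of the list was -0.10 and -0.09 in the replicates, and 29 of the 40 were lower in both. It gave camera adjusted p = 0.0079, or 0.00361 with the block, and adjusted p = 0.898 with an estimated correlation. Without TGF-β1 replicate 1 its adjusted p was 0.294, and without vehicle replicate 2 it was 0.208. Of 40 genes of G2/M and mitosis, 0 rose and 2 fell, with the same counts adjusted over the list alone and 0 and 1 in blocked DESeq2 (camera adjusted p = 0.816).

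Among 14 cell cycle inhibitors, 3 rose and 1 fell, with the same counts adjusted over the list alone and 2 and 0 in blocked DESeq2. CDKN1C rose 5.98-fold and 3.09-fold from 0.690 and 1.69 CPM, BTG2 rose 1.75-fold and 1.69-fold, and GADD45B rose 1.85-fold and 1.36-fold. CDKN1A, CDKN1B and CDKN2B did not pass, with log2 changes of -0.09 ± 0.16, 0.11 ± 0.08 and 0.27 ± 0.26 (SE, edgeR with the block), nor did RBL2, at 1.10-fold and 1.11-fold. The list did not pass camera (adjusted p = 0.133).

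Of 22 p53 targets, 5 rose and 1 fell, or 5 and 2 when adjusted over the list alone and 1 and 0 in blocked DESeq2 (camera adjusted p = 0.608). Of 16 BCL2 family genes, 3 rose and 2 fell, or 4 and 2 when adjusted over the list alone and 2 and 1 in blocked DESeq2 (adjusted p = 0.465), and the BCL2-binding factor BMF rose 4.66-fold and 3.75-fold. Of 17 genes of JAK-STAT5 and erythropoietin signalling, 4 rose and 2 fell, with the same counts adjusted over the list alone and 3 and 0 in blocked DESeq2 (adjusted p = 0.405). Of 32 actin, adhesion and integrin genes, 5 rose and 8 fell, or 5 and 10 when adjusted over the list alone and 2 and 6 in blocked DESeq2 (adjusted p = 0.193).

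The largest rises with the block were in genes of low vehicle expression. C3, complement component 3, had 3 and 160 counts in vehicle and TGF-β1 replicate 1, and 23 and 732 in replicate 2. Its replicate 1 ratio of scaled counts was 61.4, with an exact 95% counting interval from 20.6 to 301. The hair growth regulator HR rose 9.91-fold and 14.8-fold, from 1.14 ± 0.439 to 14.0 ± 1.29 CPM (SD, n = 2), and the keratin KRT79 6.52-fold and 6.09-fold. The retroviral gene ERVE-1 rose 11.1-fold and 12.0-fold, and the transporter ABCC3 5.29-fold and 2.97-fold. FAM43A, PPFIBP2, CARNS1, AGPAT4-IT1 and LRRN2 rose between 4.37-fold and 6.14-fold in the blocked fit.

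Of the genes with the largest falls, the cell adhesion gene NECTIN1 was the most abundant. NECTIN1 (ENSG00000110400.10, protein coding, chromosome 11, 119623408 to 119729084, minus strand, GRCh38) fell from 164 ± 14.5 to 53.6 ± 0.323 CPM (SD, n = 2), a log2 change of -1.61 ± 0.08 (SE; adjusted p = 3.17e-50, edgeR with the block). DDN fell to 0.115 and 0.301 of vehicle, the surrogate light chain gene IGLL1 to 0.297 and 0.320, and the metallothionein MT1E to 0.352 and 0.405. The caveola gene CAVIN2 fell to 0.522 and 0.377, and cyclin A1 (CCNA1) to 0.396 and 0.6. The pseudogene SCDP1, RPS6KL1, BEND3, UBASH3A, CXADR and TNS3 fell to between 0.409 and 0.482 of vehicle in the blocked fit. Exons of NECTIN1, DDN, IGLL1 and CAVIN2 overlap genes on the opposite strand.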

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

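The fits that join the replicate block to another choice were added after the data were seen; the other settings here were planned. The count of 0 genes held in edgeR under every other scaling, filter, dispersion and threshold tried without the block, and in limma-voom. DESeq2 without the block called 89 higher and 12 lower. With the replicate block the counts were 1740 higher and 1617 lower. Joined to the block, robust=FALSE gave 1757 and 1604, limma-voom 1741 and 1628, total counts 1793 and 1597, and removal of globin and mitochondrially encoded genes 1785 and 1578. A CPM minimum of 1 gave 1484 and 1276, DESeq2 659 and 607, and glmTreat at a fold of 1.2 gave 783 and 339. Leaving out a library under the block leaves no residual degree of freedom, so those calls have no such check.

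Without the block camera called 8 lists higher and 5 lower. With an estimated correlation 0 and 0 passed, and with fry 0 and 0, with the replicate block as well as without it. With no filter on low counts 5 passed as higher. With 1 library left out, 2 to 8 passed as lower, and the TGF-β/SMAD response, ID gene, interferon and MYC target lists passed in each of those 4 runs. The block changed the call of 1 list, red cell membrane genes. The correlation of the replicates' changes was 0.664 at a CPM minimum of 1 and 0.228 with no filter, which adds genes of few counts. Log2 changes without the block turned sign for 14 of 106 named genes when 1 library was left out. They ranged from -0.19 to 0.35 for HBG2, -0.63 to 1.75 for HBA1, -0.82 to 1.92 for HBA2, -0.19 to 0.16 for HBE1, -0.27 to 0.88 for GATA2, -0.047 to 0.26 for KLF1 and -0.12 to 0.40 for BCL11A. Further ranges were -0.33 to 2.76 for SLC4A1, -0.25 to 0.40 for EPOR, -0.12 to 0.15 for TFRC, -1.07 to 0.0099 for KIT, -0.79 to 0.73 for CDKN1A, -0.0022 to 0.23 for CDKN1B and -0.34 to 1.32 for CDKN2B. Some genes that kept their sign also moved far, with 0.044 to 0.46 for HBB, 0.33 to 0.98 for HBD and 0.40 to 1.78 for ALAS2. Others moved little, with -0.50 to -0.42 for MYC. Among lists whose direction turned, camera's adjusted p ranged from 0.000239 to 0.919 for heme synthesis, 0.00522 to 0.875 for erythroid transcription factors, 0.000204 to 0.892 for red cell membrane genes, 0.0288 to 0.538 for progenitor-stage genes, 1.23e-05 to 0.956 for mast cell genes and 0.195 to 0.514 for TGF-β receptors. The last also turned under the block with fry (adjusted p = 0.861). Each run with 1 library left out set unequal replicate numbers against each other. The cause of the turns was not tested beyond the offset between replicate numbers weighed under other observations.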

Other observations

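All tests of explanations in this part were chosen after the results were seen. Medians given with a bootstrap SE here are taken over list members from the log2 CPM differences within replicates, averaged over the 2 where 1 value is given, and so differ from list medians of the blocked fit. Besides SMAD6, HBZ, SKIL and AQP1, 5 more genes were at least 2-fold higher in both replicates without passing the blocked edgeR fit, which called all 9 with robust=FALSE, and they are named for that reason. IGFBP5, which binds insulin-like growth factors, went from 4.76 to 195 CPM in replicate 1 and from 8.53 to 66.8 in replicate 2. The actin-severing gene GSN went from 40.2 to 163 and from 28.0 to 204 CPM. The matrix gene FBLN2 was 11.6-fold and 4.31-fold higher, GPR153 6.15-fold and 2.44-fold, and AGPAT4 5.57-fold and 2.78-fold. Blocked DESeq2 gave these 5 genes adjusted p from 2.14e-07 for GSN to 0.0275 for GPR153.

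Lists that did not move one way as a whole still held single genes that passed with the block, named after their values were seen. Of the integrins, ITGB8 fell to 0.248 and 0.335 of vehicle from a low level, and ITGA4 to 0.629 and 0.709, while ITGA5 rose 1.5-fold and 1.93-fold. The STAT5 target CISH rose 1.73-fold and 1.59-fold, and SOCS1 rose 1.83-fold and 2.63-fold. CISH passed without the block when adjusted over its list alone (adjusted p = 0.0495 in edgeR), which takes no account of the 34 lists tested. The stem cell marker CD34 rose 1.30-fold and 1.80-fold, from a mean of 6.62 CPM with vehicle to 9.50 with TGF-β1, and did not pass in blocked DESeq2. The p53 target TP53INP1 rose 1.95-fold and 1.82-fold, and EGR3 fell to 0.521 and 0.564.

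The first pattern weighed is that 0 genes passed without the replicate block and 3357 with it. An offset between the replicate numbers may account for this, since the replicate differences of the vehicle and TGF-β1 libraries correlated across genes at r = 0.811. Against mostly noise among the 2489 calls of mean CPM of at least 5, as many such genes chosen by the size of their change in 1 replicate moved the same way in the other in 88.9% of cases or more. Chosen from all tested genes, 3357 genes did so in 73.9% and 74.4%, so weaker calls of low genes may hold more noise. Whether the offset comes from donor, culture or library preparation stays open.

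The second pattern is the higher level of globin, heme and red cell membrane genes as a group, with medians of 0.19 ± 0.05 and 0.26 ± 0.05 (log2, bootstrap SE over genes) in the replicates. The bootstrap treats genes as independent, and camera with an estimated correlation gave each of these lists adjusted p = 0.898. A trend with transcript length or GC content is argued against, since the median was 0.22 ± 0.06 after it was removed. Fewer cells of other lineages could also raise erythroid shares; the mast cell median was 0.30 ± 0.17, the neutrophil median 0.06 ± 0.12 and the megakaryocyte median -0.10 ± 0.13, which decides neither way. A shift along the axis on which the replicates differ, such as earlier maturation of the treated cultures, also stays open, with a Pearson r of 0.121 and a Spearman rho of 0.0972 across 11649 genes outside these lists, on either side of the bound of 0.1 set for the Pearson r. An effect of TGF-β1 on erythroid genes remains a hypothesis beside these.

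The third pattern is the lower level of MYC targets as a group, with a median of -0.34 ± 0.02. The bootstrap SE treats genes as independent, and camera with an estimated correlation gave the list adjusted p = 0.252. A trend with length or GC content is argued against, the median being -0.34 ± 0.02 after its removal. Fewer cycling cells at the size of the fall is argued against by the G2/M and mitosis genes, whose median was 0.00097 ± 0.02. The G1/S and DNA replication genes did fall by less, with a median of -0.098 in the blocked fit. Of these 40 genes, 29 were lower in both replicates, so a smaller change in cycling is not excluded. A lower MYC activity 12 h after TGF-β1 may be the source, in line with MYC at 0.704 and 0.752 of vehicle. No test here separates it from a general fall of ribosome assembly genes by another route.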
